A study of Mus musculus with 24 samples.

How the data were processed

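RNA abundance was measured in 24 mouse samples on a custom NimbleGen array with 12 wells per slide. Total RNA came from whole brain, liver, epididymal white adipose tissue and gastrocnemius muscle, per the labels' protocols. It was copied into biotin-labelled cRNA before hybridisation, per the labels' protocols. The series design text states 3 biological replicates for each genotype and tissue, so p-values measure the spread between samples of different animals as far as that statement goes. Groups were taken from the sample titles: B6 or congenic, in each of the 4 tissues. The treatment field calls all 24 samples congenic, those titled B6 included, and the growth protocol speaks of F2 mice, so the genotype of each sample rests on its title and source name. The labels' growth protocol, the same for all samples, mentions a chow diet and a high fat diet given to some congenic males. It ties no sample to a diet or sex, so a difference in diet between the groups can be neither stated nor excluded here.

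The deposited per-sample files hold scanner intensity values on a linear scale, as the mean brightness of the probes of an exon, per the file headers. Each file lists 3919 exon rows built from 13388 probes, with 2 to 14 probes per row and 3 as the most frequent number. The difference column equalled the perfect-match column in 100% of the rows, so no mismatch signal had been subtracted from these values. Whether another background had been removed before export cannot be told from this. The deposited series matrix holds the authors' intensity values per probe on a linear scale. Its column medians lie between 438.6 and 441.3, as after a normalization between arrays, and single-channel values on this scale have no direction or gene centring to settle. RMA is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The genome build of the exon coordinates is likewise not given in the sources used here.

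The exon intensities were corrected with normexp (offset 50), quantile normalized over the 24 arrays and taken to log2. Exon rows with identical coordinates in a gene were averaged, which left 3099 exon features. Median polish over the features of a gene then gave 1 value per gene and array. Of 523 transcripts, 483 had a gene symbol in the platform annotation and 40 had none. Of the value table's probes, 12649 had 1 gene symbol, 739 had none and 0 had several. Symbols were updated by gene ID through a RefSeq table of GRCm38, which held 300 of the 301 symbols. No coordinates were taken from that table. The 341 genes tested were the 301 with a symbol and the 40 transcripts without a symbol, 333 on chromosome 2 and 8 elsewhere.

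Genotypes were compared with limma 3.58.1 in R 4.3.3, in a fit with a mean for each of the 8 groups and a spread shared by all groups. Benjamini-Hochberg adjusted p under 0.05 over the 341 genes was the threshold throughout. Contrasts were congenic minus B6 within each tissue, their mean over the 4 tissues, the genotype by tissue interaction and the differences between tissues. Of 14 gene lists of cell types and pathways, 8 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, camera with an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

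The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to come later. The rule named up to 10 higher and 10 lower genes per comparison among those past the threshold. Where fewer than 5 genes passed, it added the 3 smallest p-values in each direction. Between tissues it took the 4 genes per tissue with the largest excess over the highest of the other tissues, and of each gene list up to 4 members. Pcsk2 was also on the rule and was not analysed here.

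Array brightness differed widely: the median raw intensity ran from 232 to 3571, a ratio of 15.4. The precision of each contrast is limited by the 3 arrays per group. Brain and liver samples were on slide 1 and adipose and muscle samples on slide 2. Each genotype comparison therefore lies within a slide, and slide as a block could not be fitted within a tissue. Tissues on different slides cannot be told apart from the slides. On slide 1 the 4 arrays of well row A were congenic, while the rows of slide 2 held both genotypes.

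Each scanner file was set against the columns of the value table. Of the 24 files, 7 matched the column of their own replicate best, 17 matched another replicate of their own group, and 0 matched another group. Replicate numbers were therefore used only as names in the main fit. The alternatives with a replicate block or with correlation across tissues take the numbers as given. They cannot settle whether samples pair or share animals. Between replicates, the correlation of raw log2 values ran from 0.920 to 0.989.

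The fit was tested on simulated data made from the real exon residuals, with 60 of the 341 genes changed. With residuals drawn without replacement, simulated changes of 1 log2 unit were recovered in 100% of cases in each tissue. Changes of 0.5 were recovered in 87.3% of cases for brain, 86.7% for liver, 84.0% for adipose and 86.0% for muscle. With 60 genes truly changed, the mean number of unchanged genes called was 7.6 for brain, 11 for liver, 1.8 for adipose and 2.2 for muscle. With residuals drawn with replacement, which was run before, false calls numbered 5.4, 11.6, 3.6 and 3.8. The draw without replacement was added because of those counts, and it left more false calls in brain and liver than in the other tissues. The spread within groups differed by tissue, with a median residual SD of 0.122 log2 units in brain, 0.126 in liver, 0.0908 in adipose and 0.0786 in muscle. A spread shared by all groups is thus too small for brain and liver, and the number of false calls there exceeded the stated rate in the simulation. Contrasts with fewer changed genes were not simulated. The fit with only the 6 samples of a tissue does not share this property and is given beside the brain and liver counts.

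The alternatives were the value table, no background correction, a normexp offset of 16, median scaling, quantile normalization within each tissue, the mean of the exons, removal of dim genes, each sample left out, a replicate block, only the samples of a tissue and correlation across tissues. Alternatives chosen after seeing the data were a block for slide and well row, removal of congenic adipose replicate 1 together with congenic muscle replicate 3, comparisons of tissues within a slide, and the whole analysis of single exons.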

Results

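Gene expression was measured in B6 mice and in congenic mice of the B6.S-2 strain, in whole brain, liver, epididymal white adipose tissue and gastrocnemius muscle, with 3 samples per genotype and tissue. A congenic strain carries a stretch of chromosome from another strain on a background such as B6, and the series title places the work in a search, by position, for genes that affect weight and fat mass. The labels do not state the ends of the donor segment. The array covered 333 genes of chromosome 2, from base 121896708 to base 167412296 in the coordinates of the deposited files (build not given in the sources used here). Another 8 genes, such as Ppia and Tbp, lay on other chromosomes. Changes are congenic minus B6 on the log2 scale with the standard error of the limma fit, n = 3 per group. The median raw intensity of an array ran from 232 to 1237 on slide 1, which held brain and liver, and from 916 to 3571 on slide 2, which held adipose tissue and muscle.

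The tissues differed in most of the genes measured. Muscle had the calcium-binding troponin subunit Tnnc2 5.19 ± 0.05 log2 units above the mean of the other tissues and the myosin kinase Mylk2 1.88 ± 0.06 above it. Liver had Ahcy, an enzyme of methionine metabolism, 2.79 ± 0.09 higher, the lipopolysaccharide-binding protein gene Lbp 1.16 ± 0.09 higher and the transcription factor gene Hnf4a 0.64 ± 0.04 higher. Brain had Napb, which acts in synaptic vesicle fusion, 1.65 ± 0.08 higher, the noncoding RNA Snhg11 1.56 ± 0.08 higher and Ndrg3 0.95 ± 0.05 higher. Adipose samples had the beta-defensin gene Defb20 4.29 ± 0.16 higher, the protease inhibitor gene Spint4 3.98 ± 0.14 higher and the cystatin gene Cst11 4.01 ± 0.11 higher. Defb20 and Cst11 belong to the list of epididymis and testis genes, not to that of adipocytes.

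Of the 341 genes, 244 differed between tissues (limma F test, Benjamini-Hochberg). Of the lists fixed beforehand, 3 of 3 skeletal muscle genes were higher in muscle, 5 of 8 neuronal genes in brain, 2 of 3 hepatocyte genes in liver and 4 of 5 endothelial genes in adipose tissue. The third hepatocyte gene, Foxa2, was higher in muscle. Of 11 epididymis and testis genes, 6 were higher in the adipose samples, namely Cst11, Cst12, Defb20, Defb21, Defb22 and Eppin. Of 2 glial genes Cst3 was higher in brain, and of 4 immune genes B2m was higher in adipose tissue and in liver, Samhd1 in adipose tissue and in muscle, and Cst7 in muscle. Of 4 adipocyte genes 1 was higher in adipose tissue, Pltp, and 2 were lower there and higher in muscle, the acetate-activating enzyme genes Acss1 and Acss2. The other genes named by the rule were Cst3 in brain, Sdc4 in liver, the transcript BC049753 without a symbol in adipose, and Eif2s2 and Cse1l in muscle. Because adipose and muscle shared slide 2, and brain and liver slide 1, comparisons within a slide were added after seeing the data. Brain and liver differed in 117 genes, 59 of them higher in brain, and adipose and muscle in 123, 54 of them higher in adipose. Within slide 2, Tnnc2 was lower in adipose than in muscle by a log2 difference of -4.98 and Cst11 higher by 3.69. Of the list genes above, 5 did not pass within their slide: Slc24a3 of the neuronal list between brain and liver (adjusted p = 0.0984), and between adipose and muscle the endothelial Thbd (adjusted p = 0.159) and Id1 (adjusted p = 0.0738), Foxa2 (adjusted p = 0.339) and Samhd1 (adjusted p = 0.828).

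In brain, 3 genes fell in congenic mice and 0 rose. Napb fell by 0.63 ± 0.13 (limma, adjusted p = 0.0237), a level 1.55-fold lower. Snhg11 fell by 0.62 ± 0.14 (adjusted p = 0.0237), and the transcript AK016198, which has no symbol here, by 0.55 ± 0.12 (adjusted p = 0.0237). All 3 lie on chromosome 2, Napb at 148447215 to 148484979 and Snhg11 at 158439030 to 158444939.

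At an unadjusted p under 0.05, 37 of the 341 genes differed in brain. The smallest p-values short of the threshold belonged to Ppia at 0.79 ± 0.20 (limma, adjusted p = 0.0846), Sec23b at 0.23 ± 0.08 and AK045769 at 0.36 ± 0.13 on the higher side. On the lower side they belonged to Cst13 at -0.44 ± 0.14, 6820408C15Rik at -0.20 ± 0.07 and Tspyl3 at -0.29 ± 0.11. Napb was also the single member past the threshold among 8 neuronal genes and 14 vesicle traffic genes. It was likewise the 1 member of either list when adjusted over the list alone. None of the lists shifted in brain: 0 of 8 passed with camera, camera with an estimated correlation, or fry. At an unadjusted p under 0.05 the counts were 1, 0 and 0, the list of camera being RNA processing and translation (adjusted p = 0.200, and adjusted p = 0.460 with an estimated correlation). With only the 6 brain samples 0 genes passed in limma (20 at an unadjusted p under 0.05), with median scaling 0 passed (22), and with the well row as a block Snhg11 and AK016198 were lost, on a slide whose row A held only congenic samples. Without B6 brain replicate 3 the change of Napb was -0.39, and its call was lost in 10 of the 24 fits that each left out an array. Over the alternatives Napb ran from -0.79 to -0.36, Snhg11 from -0.88 to -0.39, AK016198 from -0.57 to -0.35, Ppia from 0.36 to 0.79 and Sec23b from 0.15 to 0.27, and without B6 brain replicate 3 Tspyl3 was -0.17.

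In liver, 2 genes rose and 0 fell. Hnf4a, a transcription factor of hepatocyte identity, rose by 0.48 ± 0.07 (limma, adjusted p = 8.43e-04), from 9.72 ± 0.10 in B6 to 10.20 ± 0.11 in congenic liver (SD, n = 3). The gene 9430021M05Rik rose by 0.47 ± 0.10 (adjusted p = 0.0141). They lie near each other on chromosome 2, at 163570196 to 163636254 and at 162724511 to 162730458. The median raw intensity was 454, 232 and 294 on the B6 liver arrays and 456, 741 and 667 on the congenic ones. Each congenic liver array was thus brighter than each B6 liver array before normalization, and brightness cannot be fully told apart from genotype there.

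Short of the threshold stood Spag4 at 0.29 ± 0.07 (limma, adjusted p = 0.0526), the agouti gene a at 0.49 ± 0.13 (adjusted p = 0.0951) and Scand1 at 0.43 ± 0.12 on the higher side. Cst3 at -1.04 ± 0.27 (adjusted p = 0.0951), Map1lc3a at -0.41 ± 0.11 and Serinc3 at -0.51 ± 0.15 (adjusted p = 0.116) stood on the lower side. At an unadjusted p under 0.05, 45 genes differed. Hnf4a was 1 of 3 measured hepatocyte genes, and the other 2, Foxa2 and Ahcy, did not pass. Adjusted over the list alone, Hnf4a, Cst3, Spag4, Tpx2 and a each passed in their lists. None of the lists shifted in liver: 0 of 8 passed with camera, camera with an estimated correlation or fry, and 0 had an unadjusted p under 0.05 with any of them. With only the 6 liver samples 0 genes passed in limma (21 at an unadjusted p under 0.05), and over the alternatives the adjusted p of Hnf4a ran from 1.26e-05 to 0.128. The call of 9430021M05Rik held in 5 of 11 alternatives, with changes of 0.22 to 0.87, and was lost with the well row as a block, with median scaling, with the value table and without 2 arrays high in seminal vesicle genes. The change of a was 0.047 with the value table and 0.32 without congenic liver replicate 1, and that of Scand1 was 0.26 without B6 liver replicate 1.

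In adipose tissue, 4 genes fell and 1 rose. Serinc3, which encodes a membrane protein of the serine incorporator family, fell by 0.93 ± 0.15 (limma, adjusted p = 0.00172), a level 1.90-fold lower, from 12.18 ± 0.23 to 11.25 ± 0.28 (SD, n = 3). Adig, which encodes the adipocyte protein adipogenin, fell by 0.41 ± 0.08 (adjusted p = 0.00872). The cystatin-family gene Cstdc2 fell by 0.93 ± 0.22 (adjusted p = 0.0306; -2.48 to -0.82 over the alternatives) and the beta-defensin gene Defb29 by 0.43 ± 0.09 (adjusted p = 0.0124). The zinc finger gene Zfp937 rose by 0.55 ± 0.13 (adjusted p = 0.0416).

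At an unadjusted p under 0.05, 27 genes differed in adipose tissue. Of the 11 epididymis and testis genes, 0 passed, although Cstdc2 and Defb29 belong to the same gene families as some of them. Of 4 adipocyte genes, 0 passed over all genes, and Pltp at 0.47 ± 0.12 passed when adjusted over the list alone. In adipose tissue 0 of 8 lists shifted with camera, camera with an estimated correlation or fry, and 0 had an unadjusted p under 0.05 with any of them. In congenic adipose replicate 1 and congenic muscle replicate 3, genes of the seminal vesicle secretion were high, with Svs4 at 12.43 and 12.89 against B6 means of 10.28 in adipose and 9.68 in muscle. Without these 2 arrays, a check added after seeing the data, 10 genes passed in adipose tissue, of which 4 were among the 5 above and 2 were Svs4 and Svs5, and Zfp937 was lost. With the well row as a block, Cstdc2 and Zfp937 were lost, and with only the 6 adipose samples Serinc3 (adjusted p = 0.0881, and up to 0.233 over the alternatives) and Cstdc2 were.

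In muscle, 2 genes fell and 0 rose. Serinc3 fell by 0.77 ± 0.15 (limma, adjusted p = 0.00850), a level 1.71-fold lower. Uqcc1, an assembly factor of mitochondrial complex III, fell by 0.52 ± 0.08 (adjusted p = 7.71e-04), from 9.85 ± 0.01 to 9.34 ± 0.07 (SD, n = 3). Uqcc1 lies at 155910243 to 155993612 of chromosome 2 and Serinc3 at 163686621 to 163708480.

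Short of the threshold stood Znfx1 at 0.52 ± 0.13 (limma, adjusted p = 0.0607), Nxt1 at 0.37 ± 0.12 and 4930556L07Rik at 0.24 ± 0.08 on the higher side. Nfs1 at -0.27 ± 0.07 (adjusted p = 0.0732), Mylk2 at -0.38 ± 0.10 (adjusted p = 0.115) and Tti1 at -0.35 ± 0.10 stood on the lower side. At an unadjusted p under 0.05, 17 genes differed. Of 3 skeletal muscle genes 0 passed over all genes, and Mylk2 passed when adjusted over the list alone. In muscle 0 of 8 lists shifted with camera, camera with an estimated correlation or fry, and 0 had an unadjusted p under 0.05 with any of them. The call of Serinc3 was lost without B6 brain replicate 3, B6 muscle replicate 3 or congenic muscle replicate 1, with an adjusted p of up to 0.0745. Over the alternatives Nxt1 ran from 0.12 to 0.50, Nfs1 from -0.43 to -0.23, Mylk2 from -0.70 to -0.34 and Tti1 from -0.41 to -0.13.

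**Figure D1:**
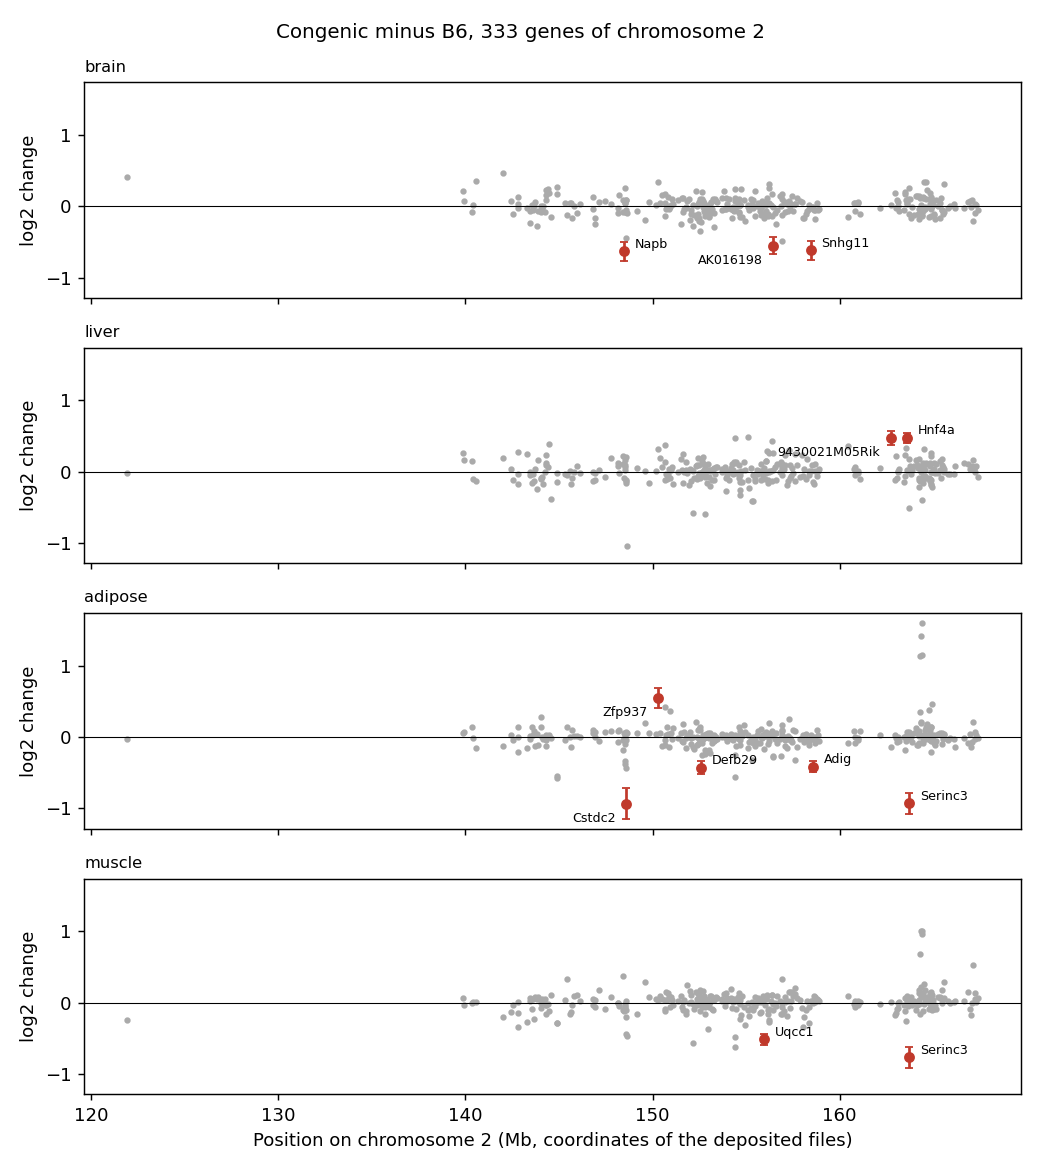
Change in congenic against B6 mice (log2, y axis) of each of 333 chromosome 2 genes at the middle of its position in Mb (x axis), 1 panel per tissue. Red points with standard errors are the genes past the adjusted threshold, 3 in brain, 2 in liver, 5 in adipose and 2 in muscle, and grey points are the others.

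Averaged over the 4 tissues, 7 genes differed between genotypes, 3 higher and 4 lower. This average treats the 24 samples as independent. The labels do not say whether the same animals gave all 4 tissues, and if they did, the p-values overstate the number of animals. Serinc3 fell by 0.49 ± 0.07 (limma, adjusted p = 8.29e-04), Srxn1, which encodes an antioxidant enzyme, by 0.39 ± 0.09 (adjusted p = 0.0269), Uqcc1 by 0.20 ± 0.04 (adjusted p = 0.0104) and Defb29 by 0.18 ± 0.04 (adjusted p = 0.0357). Zfp937 rose by 0.31 ± 0.07 (adjusted p = 0.0162), Hnf4a by 0.17 ± 0.04 (adjusted p = 0.0162) and Spag4 by 0.14 ± 0.03 (adjusted p = 0.0298). At an unadjusted p under 0.05, 51 genes differed. Of 11 alternatives, Serinc3 and Uqcc1 passed in each, Zfp937 in 10 (lost with the well row as a block), Hnf4a and Srxn1 in 9, Spag4 in 8 (0.074 to 0.18) and Defb29 in 5 (-0.19 to -0.047). Leaving out an array ended the call of Defb29 in 16 of 24 fits, of Spag4 in 12 and of Srxn1 in 7. The passing genes lay between 150 and 165 Mb, 3 in the window from 150 to 155 Mb, 2 from 155 to 160 Mb and 2 from 160 to 165 Mb, windows that held 97, 74 and 68 measured genes.

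The genotype difference of Serinc3 varied between tissues (limma interaction F test, adjusted p = 0.0330). It was 0.25 ± 0.15 in brain, -0.51 ± 0.15 in liver, -0.93 ± 0.15 in adipose and -0.77 ± 0.15 in muscle. It was the 1 gene of 341 past the threshold, with 29 at an unadjusted p under 0.05. Hnf4a (adjusted p = 0.113) and Uqcc1 (adjusted p = 0.104) did not pass here, and both passed with the value table and with the mean of the exons, where 6 and 5 genes did. The count was 0 with the well row as a block (limma, 35 at an unadjusted p under 0.05) and after leaving out any of 14 of the 24 arrays (25 to 36).

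**Figure D2:**
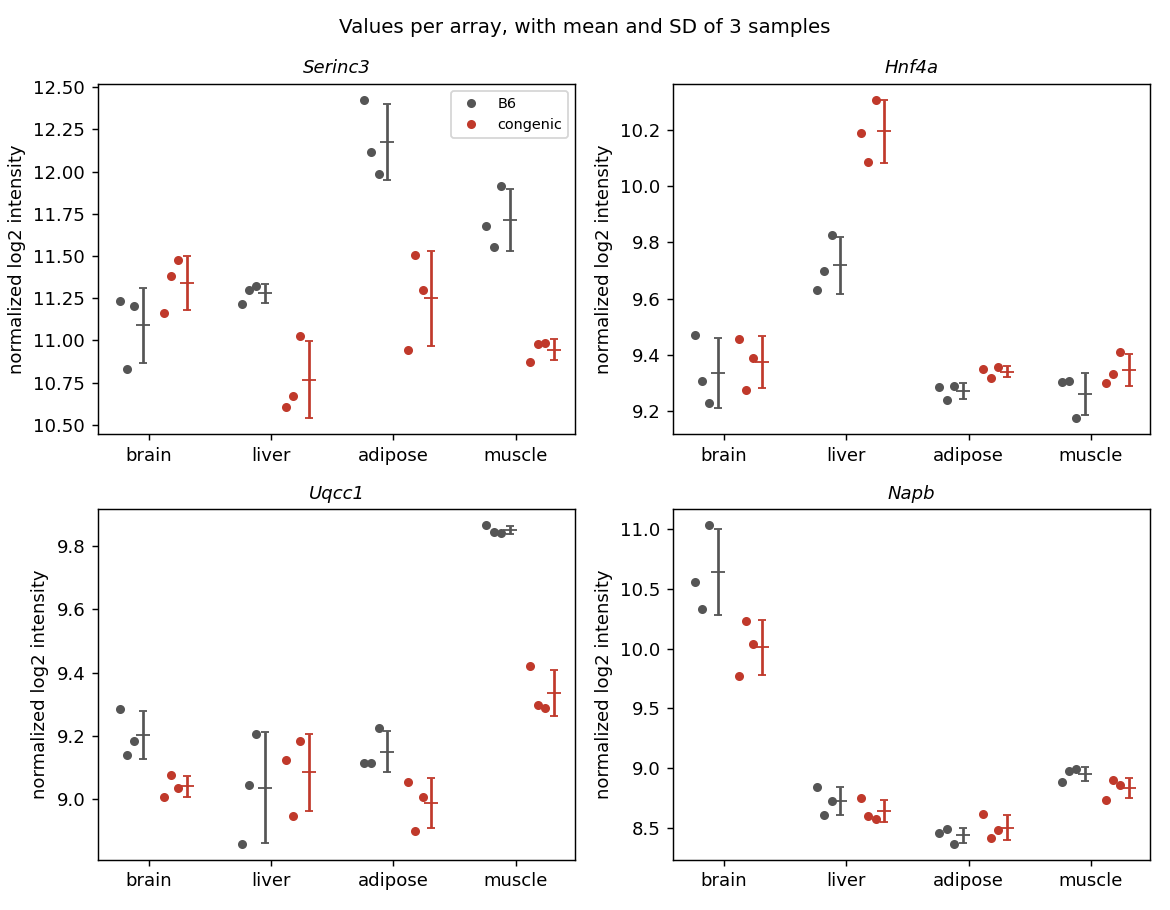
Normalized log2 intensity (y axis) of Serinc3, Hnf4a, Uqcc1 and Napb in each sample by tissue (x axis), with B6 in grey and congenic in red, and bars for the mean and SD of 3 samples. Congenic Serinc3 means of 11.25 in adipose and 10.95 in muscle lie below the B6 means of 12.18 and 11.72, and in brain the congenic mean of 11.34 lies above 11.09.

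Single exon features were compared after the gene results had been seen. Averaged over tissues, 38 of 3099 features in 26 genes passed, 34 lower and 4 higher in congenic samples. By tissue, 7 of 11 features called were lower in brain, 19 of 32 in liver, 11 of 12 in adipose and 11 of 11 in muscle. Of the changes averaged over tissues, the farthest from 0 was in a feature of 25 bases of Eif2s2, which encodes a subunit of translation initiation factor 2, at 154951685 to 154951709. It fell by 2.68 ± 0.17 (limma, adjusted p = 8.95e-10), with differences of -3.16 in brain, -2.75 in liver, -2.59 in adipose and -2.20 in muscle. A feature of 179 bases that ends at the same base and covers it stood at 0.35 ± 0.14 (adjusted p = 0.338). Of the other features of the gene, 2 passed: they fell by 0.87 ± 0.20 (adjusted p = 0.0309) and by 0.73 ± 0.11 (adjusted p = 7.26e-04). The median change of the other features of Eif2s2 was 0.0033, and the gene did not pass in any tissue. Features of Rbm39 at -1.09 ± 0.12, Naa20 at -0.92 ± 0.12 and Crnkl1 at -0.95 ± 0.14 also fell, in genes that did not pass. Genes that passed also changed unevenly on average over tissues. Called features stood at -0.45 in Uqcc1 and at -0.59 and -0.47 in Napb, against medians of -0.14 and -0.15 for the other features. In Srxn1 it was -0.45 against -0.18, and in AK016198 -0.36 against -0.094. Whether the whole transcript of these genes changed within a tissue was not tested. In Serinc3, 7 of 11 exons passed the threshold as lower in adipose, 5 in muscle, 3 in liver and 0 in brain. By sign alone, 11 exons were lower in adipose, 10 in muscle, 8 in liver and 2 in brain.

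**Figure D3:**
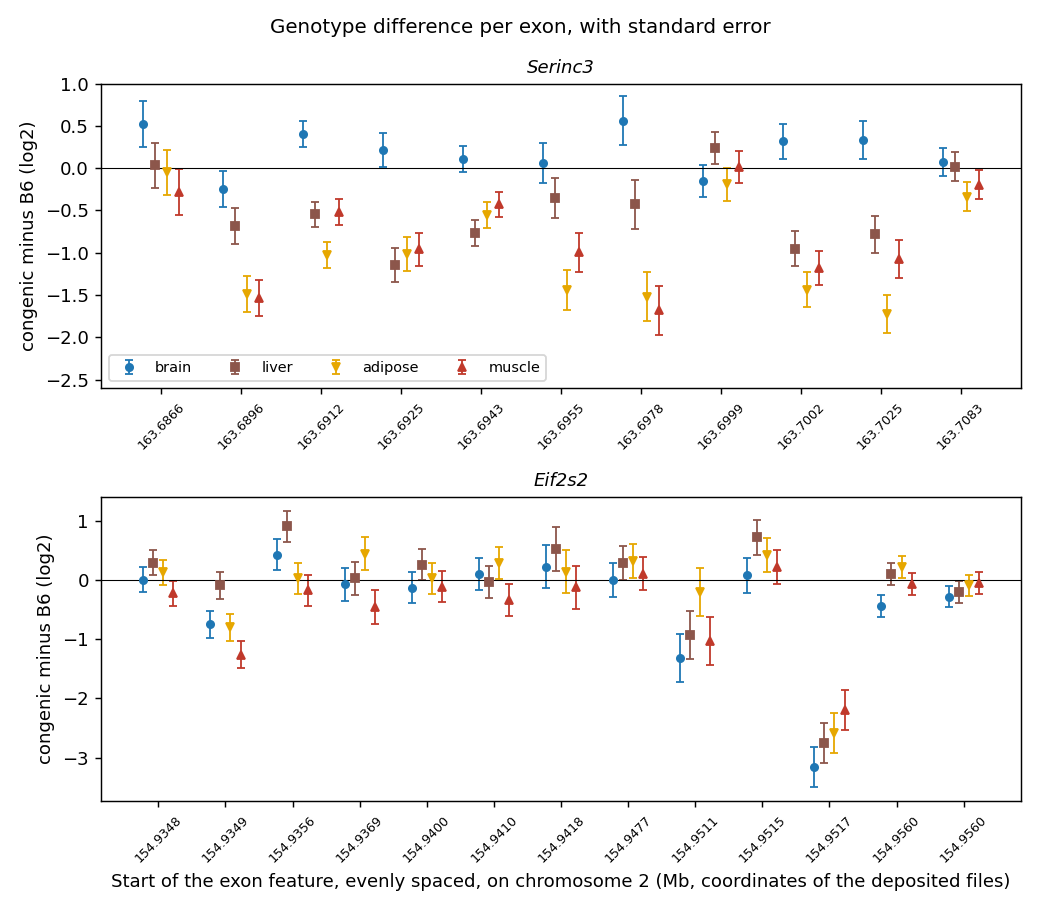
Congenic minus B6 difference (log2, y axis) of each exon feature of Serinc3 and Eif2s2 in the order of its start on chromosome 2 in Mb (x axis, evenly spaced), in 4 tissues, with standard errors. Most Serinc3 exons lie below 0 in liver, adipose and muscle, with medians of -0.55, -1.02 and -0.96, and the median in brain is 0.22, while in Eif2s2 the feature of 25 bases stands at -2.20 or lower in each tissue.

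**Figure D4:**
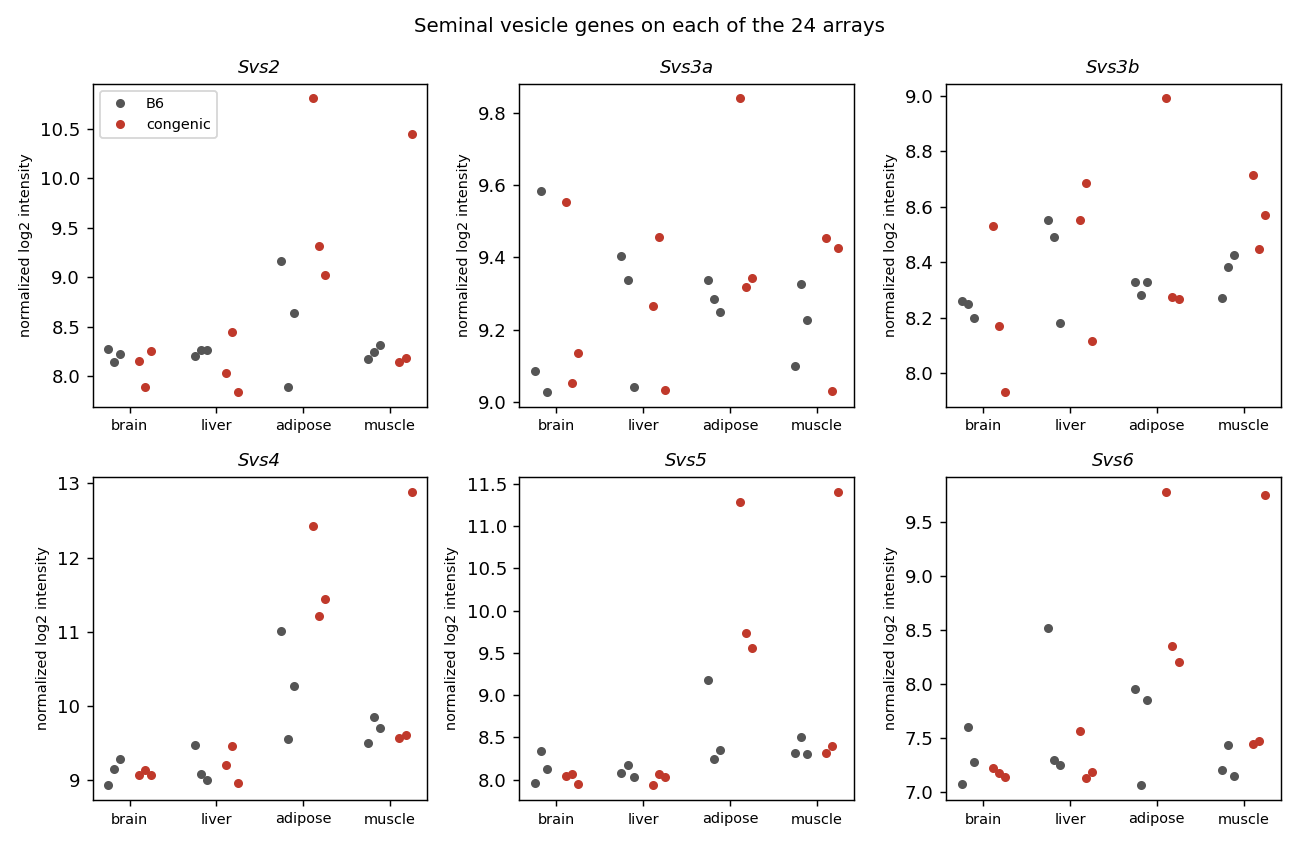
Normalized log2 intensity (y axis) of 6 seminal vesicle genes on each array by tissue (x axis), with B6 in grey and congenic in red. Congenic adipose replicate 1 and congenic muscle replicate 3 stand apart, as for Svs5 at 11.29 and 11.41 against 9.65 and 8.35 for the means of their group mates.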

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

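The test of sequence differences for Serinc3 and the well row block were chosen after the result was seen, and Serinc3 was noticed while exploring the data. Serinc3 stood out because its genotype difference varied between tissues (limma interaction test, adjusted p = 0.0330), with a lower level in congenic liver, adipose and muscle and not in brain. The lower level in liver did not pass in the main fit, and it passed in 2 of 11 alternatives. Sequence differences under the probes would lower the same exons in every tissue, yet the median exon change in brain was 0.217. That test rests on the difference between brain and the other tissues. On the slide of brain, row A held only congenic arrays, so such sequence differences cannot be excluded by it. Background correction and normalization would end the call in some setting, but the highest adjusted p (limma) of the mean change over 5 such alternatives was 0.00264. No alternative left out both background correction and quantile normalization, so their joint effect was not tested. Position on the slides would shrink the change, and with slide and well row as a block the mean change was -0.558. That answers only for the mean over tissues: with the same block, 0 genes passed the limma interaction test. Position therefore stays open for the variation between tissues. A difference of genotype in Serinc3 RNA may remain as a hypothesis, found and tested on the same data. Its variation between tissues is less certain: 19 of 100 splits within tissues gave at least the 1 gene found, with up to 8. Chance could therefore not be excluded for that count.

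For the genes called on average over the 4 tissues, 1 of 100 splits within tissues, the real one, gave as many as 7 genes. The highest of the others gave 2. Genotypes were shuffled in each tissue separately, so chance can be excluded at that level only if different animals gave the tissues, which the labels do not state. Position is not covered by these splits, since row A of slide 1 held only congenic arrays. For the differences between tissues, 1 of 100 splits gave as many as 244 genes, and the highest of the others gave 28. Groups of 3 samples were not tested for outliers. Within a tissue, 3 samples against 3 make 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 3 and 6 in brain, 2 and 3 in liver, 5 and 1 in adipose, and 2 and 1 in muscle, and as many genes came from 2, 2, 1 and 1 of the 10 splits.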

How the results depend on the processing

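Chosen after seeing the data were the well row block and the removal of congenic adipose replicate 1 with congenic muscle replicate 3. Counts of genes moved as follows, from causes not tested except where fewer samples enter. With the value table the count was 8 in liver, 9 in adipose, 4 in muscle, 16 on average and 6 for the interaction. Without background correction it was 1 in brain, 5 in muscle and 2 for the interaction. With median scaling it was 0 in brain (limma, 22 genes at an unadjusted p under 0.05). With quantile normalization within each tissue it was 1 in brain, 4 in liver and 4 in muscle. With the mean of the exons it was 5 in liver, 6 in muscle, 15 on average and 5 for the interaction. Without the 2 arrays it was 1 in liver, 10 in adipose and 4 for the interaction. With the well row block it was 1 in brain (Napb), 3 in adipose and 0 for the interaction (35 at an unadjusted p under 0.05), while the 2 genes in liver were Hnf4a and Spag4. With only the 6 samples of the tissue it was 0 in brain, 0 in liver and 3 in adipose, with 20 and 21 genes at an unadjusted p under 0.05 in brain and liver. With the correlation within genotype and number over tissues it was 12 on average. Replicate numbers were not taken to pair the samples, since 5 of 12 pairs of the same number correlated above 0.1. In adipose the pairs correlated at 0.514, 0.236 and 0.0915, and both genotypes had replicates 1, 2 and 3 in well rows C, B and A. With the replicate block on all samples the count was 3 in brain, 2 in liver, 3 in adipose (without Cstdc2 and Zfp937), 3 in muscle and 11 on average. With it on only the 6 samples of a tissue it was 0 in brain, 0 in liver, 3 in adipose (Zfp937, Svs4 and Svs5, without Adig, Defb29, Cstdc2 and Serinc3) and 0 in muscle (adjusted p = 0.0818 for both genes), with 17 in brain, 24 in liver and 36 in muscle at an unadjusted p under 0.05; as fewer samples enter, the loss is not put down to the block. Leaving out each array gave 0 to 4 genes in brain, 2 to 5 in liver, 2 to 7 in adipose, 1 to 5 in muscle, 4 to 13 on average, 0 to 3 for the interaction and 227 to 250 between tissues, and 0 to 0 lists. The brain count was 0 without B6 brain replicate 3, congenic adipose replicate 3, B6 adipose replicate 2, B6 adipose replicate 3 or congenic brain replicate 3, and 1 without B6 brain replicate 1 or congenic brain replicate 1. The liver count was 4 without B6 brain replicate 1 or 3 and 5 without B6 liver replicate 1 or congenic liver replicate 3. The adipose count was 2 without congenic adipose replicate 3 or B6 adipose replicate 1 and 3 without B6 adipose replicate 2. The muscle count was 1 without B6 brain replicate 3, B6 muscle replicate 3 or congenic muscle replicate 1, 4 without congenic brain replicate 1 or congenic muscle replicate 2, and 5 without congenic liver replicate 1. The average count was 4 without congenic adipose replicate 2, congenic muscle replicate 1 or B6 adipose replicate 3, 11 without congenic adipose replicate 1, 12 without congenic brain replicate 1 and 13 without congenic liver replicate 2. The interaction count was 3 without B6 liver replicate 3 or congenic liver replicate 2 and 2 without congenic liver replicate 3. Of genes called in a tissue, leaving out an array ended the call of Napb in 10 of 24 fits, Snhg11 in 8, AK016198 in 7, Zfp937 in adipose in 14, and Cstdc2, Defb29 in adipose and Serinc3 in muscle in 3 each. Directions reversed for genes short of the threshold: Cst13 in brain was 0.10 with the mean of the exons, and with the authors' values Znfx1 in muscle was -0.21, 4930556L07Rik in muscle -0.0085 and 6820408C15Rik in brain 0.038. Median scaling or normalization within tissues left the median change of all genes under 0.03 log2 units in size.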

Other observations

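The tests of exon signs across slides, of the called exons of Serinc3 and of the seminal vesicle genes, and the resampling of genes, were chosen after the result was seen, and both patterns were noticed while exploring the data. In 2 exon features of Csnk2a1, the catalytic subunit gene of casein kinase 2, congenic brain stood far above B6 brain, by 3.38 ± 0.24 at 152322024 to 152322084 (limma, adjusted p = 6.45e-09) and by 3.33 ± 0.34 at 152326531 to 152326642 (adjusted p = 3.10e-06). In liver the same features differed by 0.27 and -0.22, in adipose by 0.47 and 0.42, and in muscle by 0.16 and 0.19. The gene as a whole, at 0.22 ± 0.09 in brain and 0.22 ± 0.09 in adipose, did not pass, but it did in both with the value table, and in brain and for the genotype by tissue interaction with the mean of the exons. These features were chosen after their values were seen. The 12 B6 arrays averaged 6.75 and 6.99 log2 units at them, below the level of 9.31 that was used to remove dim genes.

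Of the single exon features called on average over tissues, 34 of 38 were lower in congenic samples, a balance that held less in liver (19 of 32) and brain (7 of 11) than in adipose (11 of 12) and muscle (11 of 11). Serinc3 alone gave 8 of the 38. Of the lower features by tissue, it gave 7 in adipose, 5 in muscle, 3 in liver and 0 in brain. Sequence differences between the donor and B6 under the probes are a candidate explanation: of 26 exons called on slide 1, 80.8% kept their sign on slide 2, against 51.5% of all exons, though only 8 of the 26 did so at a p under 0.05 there and 14 of the 26 were lower. A difference in exon use would give the same and was not tested apart from it. A change of the whole transcript, as the cause of the whole pattern, would need the other exons to move by 0.5 of the called exon's change, and they moved by a median of 0.121 (bootstrap over genes 0.0118 to 0.393, whose upper end passes the stricter bound written beforehand), while in Serinc3 it stays open, with a median of 0.742 for its 8 called exons. Neither background correction alone nor quantile normalization alone accounts for the direction on average over tissues. At least 91.2% of called exons were lower without background correction or with median scaling. Leaving out both steps at once was not tested, nor was the direction within each tissue.

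Seminal vesicle genes were high in congenic adipose replicate 1 and congenic muscle replicate 3. RNA from seminal vesicle, which lies near the epididymal fat, is a candidate source: of the 3 genes over 1 log2 unit above both group mates in both arrays, 100% were seminal vesicle genes, although the list was written after such genes had been seen. Svs3a and Svs3b, also on that list, differed from the mean of their group mates by 0.18 and -0.01 in the muscle array. Congenic genotype would raise the other congenic muscle arrays, and these differed from the B6 mean by a median of 0.00038, while in adipose it stays open, since the mates there stood above B6 by a median of 0.63 (SD 0.474), and without the 2 arrays Svs4 and Svs5 passed in adipose. Carry-over of adipose sample RNA as the source would bring the abundant adipose transcripts too, and the median level of 9 genes high in adipose in the muscle array minus that in congenic adipose replicate 1 was -2.44 (SD 0.713), against -0.19 for the seminal vesicle genes; an earlier form of this test, the excess of those 9 genes over group mates, gave 0.443, and 0.727 in B6 muscle replicate 3 of the same well row, so adipose RNA in either stays open.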
